A study of Homo sapiens with 6 samples.

How the data were processed

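Polyadenylated RNA of LX-2 cells was sequenced in 6 libraries, 3 from cells given TGF-β at a stated 5 µg/mL and 3 from cells given TGF-β and 20 µM LIG, per the labels. RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The series description uses the word transfected for TGF-β and LIG, which was read as added to the cells. The labels give no treatment time and do not say that replicates were separate cultures.

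The deposited table holds FPKM values (fragments scaled to gene length and to the library total), made by the authors, with 1 column per library, per the file headers. The submitters' processing notes name fastp, HISAT2 2.1.0, the GRCh38.p13 assembly and DESeq2 without giving their roles. The counting tool, the annotation and the use of strand are not stated. The table lists 22701 gene symbols, of which 21713 are in a RefSeq gene table of another patch of the assembly, used for names only. Coordinates, on GRCh38, and overlaps between genes came from GENCODE release 29.

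The values of each gene are whole multiples of a step, as fragments divided by gene length and library total are. Fragments were recovered on this basis for 22699 of the 22701 genes, including all 10695 kept for testing, and 99.99% of 114123 values above 0 were whole within 0.01. The totals were 38567921, 39005172 and 38698341 fragments in TGF-β replicates 1 to 3 and 38646836, 38401783 and 39260090 in LIG replicates 1 to 3. Of the kept genes, 0.51% had fewer than 30 fragments in a library. Fragments were used for depth, for marker sums and for 1 alternative, and intervals on them cover counting error only.

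Genes with a mean FPKM of at least 1 over the 6 libraries were kept (10695). They were tested on log2(FPKM + 1) with limma 3.58.1 (linear model with group only, empirical Bayes with a mean-variance trend, two-sided), LIG minus TGF-β, with Benjamini-Hochberg adjustment at 0.05. The fit had 4 residual degrees of freedom and 4.10 prior degrees of freedom. Fold changes on this scale understate the change of genes with low FPKM. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so single genes were tested only through this model. No scaling between libraries was added to the deposited values; the median log2 change of all kept genes was 0.03.

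Gene lists were compiled from general knowledge of stellate cells, TGF-β signalling, stress responses, metabolism and cell types. Of 35 lists, 31 had at least 5 kept members and were tested with camera (limma, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Members were also adjusted over the list alone. As alternatives the correlation was estimated from the data, or fry was used, which tests a list by itself. Named genes were drawn from the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, 17 fixed genes of stellate cell activation and related pathways, and up to 4 members per list with the smallest adjusted p. Genes on chromosome Y were not named, whatever their result. The groups, tests, lists, naming rule and first set of alternatives were set before the data were examined.

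This first set of alternatives held other pseudocounts (0.1 and 0.5), no filter or a mean FPKM of at least 5, rescaling to TPM, quantile normalization, median centring, limma without trend or with robust estimation, library quality weights, a log2 change of at least 1, the replicate number as a block and leaving out each library in turn. Leaving out TGF-β replicate 2 and LIG replicate 3 together, summed FPKM as a covariate, and limma voom on the recovered fragments were added after seeing the data. No library was left out of the main comparison.

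The tests were run on simulated data for this comparison, in 5 sets of 10695 genes with 200 changed in each. Of the changed genes, 37.9% were recovered at 1.25-fold, 90.4% at 1.5-fold, 99.6% at 2-fold and 100% at 3-fold, and 62 of 972 calls (6.4%) fell on unchanged genes. A list shifted by 0.4 on the log2 scale was called in 5 of 5 sets, and 0 of 140 tests of unchanged lists were called. The simulated libraries were independent draws without the structure seen in the real ones. Each simulated gene was given the median spread of genes at a similar level. The recovered shares therefore do not hold for genes that vary more. Simulated genes were also independent of each other. The list tests on them thus cannot show how often lists of correlated genes are called in error. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

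Reads shared between near-identical genes could be split in a way not stated, which leaves the actins (ACTA2, ACTC1), KRT17, the ferritins, the AKR1C genes and HSPA1A and HSPA1B uncertain. The same holds for genes that overlap others, among them ACTA2 with FAS, LOX with SRFBP1, MEST with COPG2 and TGFB1 with HNRNPUL1 on opposite strands, and DNAJB4 with GIPC2 on the same strand.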

Results

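Polyadenylated RNA was measured by sequencing in LX-2 cells, an established human hepatic stellate cell line used as a model of the collagen-producing cells of the fibrotic liver. All 6 libraries came from cells given TGF-β, a cytokine that activates stellate cells. The labels state its dose as 5 µg/mL; TGF-β is usually dosed in ng/mL, and the stated unit was not checked. In 3 of them the cells also received 20 µM ligustilide (LIG), a phthalide found in Angelica and Ligusticum roots. The comparison asks how LIG alters gene expression in TGF-β-treated LX-2 cells. No library of cells without TGF-β was analysed here, so the effect of TGF-β itself was not measured. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples. The deposited FPKM values correspond to between 38401783 and 39260090 fragments per library, with a ratio of 1.022 between the largest and the smallest total, and a kept gene held a median of 1485 fragments per library. Counting error was therefore small for most of the 10695 genes tested, which had a mean FPKM of at least 1.

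The libraries were similar, with Pearson correlations across genes of log2(FPKM + 1) between 0.9875 and 0.998. The first principal component (55.1% of the variance) set TGF-β replicate 2 and LIG replicate 3 apart from the other 4 libraries, and the second (23.8%) separated the groups. Summed FPKM was 348518 in TGF-β replicate 2 and 362034 in LIG replicate 3, against 324022 to 328949 in the others.

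**Figure D1:**
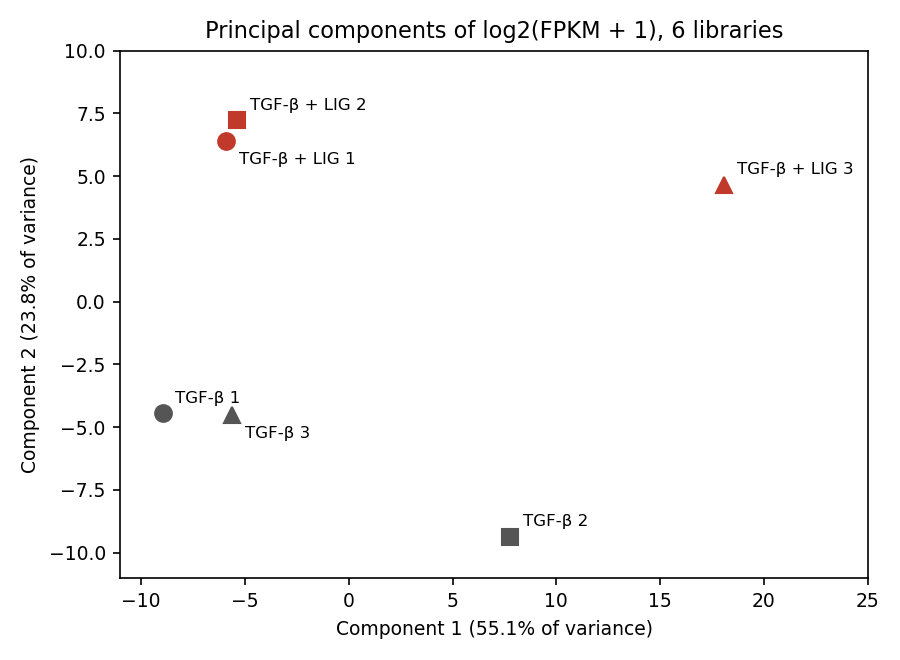
Principal components 1 (horizontal, 55.1% of the variance) and 2 (vertical, 23.8%) of log2(FPKM + 1) over 10695 genes, with 1 point per library, grey for TGF-β and red for TGF-β + LIG. TGF-β replicate 2 and LIG replicate 3 lie at positive values of component 1, and the 3 LIG libraries lie above the 3 TGF-β libraries on component 2.

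With LIG, several genes of the antioxidant response rose, and the collagen gene COL3A1 and the crosslinking gene LOX fell. The largest rise among annotated genes was in NQO1, a quinone reductase and a standard target of the transcription factor NRF2 (chromosome 16, 69706996 to 69726951). NQO1 went from 21.5 ± 1.69 FPKM (SD, n = 3) with TGF-β to 71.3 ± 7.71 FPKM (n = 3) with LIG. This is a log2 change of 1.68 ± 0.09 (SE; limma adjusted p = 0.000854). On the log2(FPKM + 1) scale tested, though not by ratio of mean FPKM, the largest fall was in IGFBP3. This gene encodes a binding protein of insulin-like growth factors (chromosome 7, 45912245 to 45921874). It went from 8.38 ± 0.63 to 3.44 ± 0.57 FPKM, a log2 change of -1.08 ± 0.10 (adjusted p = 0.00528). LOX, which encodes the lysyl oxidase that crosslinks collagen (chromosome 5, 122063195 to 122078360), went from 31.5 ± 0.92 to 14.84 ± 1.2 FPKM (log2 change -1.04 ± 0.07, adjusted p = 0.00185).

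In all, 74 of 10695 genes changed, 20 higher and 54 lower with LIG (limma, Benjamini-Hochberg adjusted, two-sided). In each of the 74, the 3 libraries of a group all lay above the 3 of the other. This was so for 15.8% of all genes tested, and chance gives 10% for 3 against 3. The 10 largest rises included NQO1, the uncharacterised loci LOC105374811 and LOC107986236, IL1B, ANGPTL4, TXNRD1, CXCL8, ESM1 and GCLM, with log2 changes from 1.68 to 0.70. LOC107986236 rests on 6 to 24 fragments per library. Among the largest falls were IGFBP3, LOX, KRT17, COL3A1, TGFB2, CPA4, the long non-coding RNA MIR503HG, MEST, NPPB and ACTC1, with log2 changes from -1.08 to -0.72. Some of these genes (NQO1, ANGPTL4, LOX, MEST and ACTC1) overlap exons of genes on the opposite strand and others (ESM1, COL3A1, TGFB2 and MIR503HG) exons on their own strand, and the labels do not say whether counting used strand. KRT17, a keratin of stressed and basal epithelia, went from 33.1 ± 1.70 to 15.9 ± 2.40 FPKM. MEST, an imprinted gene expressed in mesoderm, went from 72.0 ± 3.17 to 39.8 ± 0.41 FPKM. NPPB, which encodes B-type natriuretic peptide, went from 10.98 ± 0.38 to 6.26 ± 0.15 FPKM.

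The count changed when a single library was left out, and the 74 genes kept their direction in each such fit. Fewer libraries also mean less power, so a lower count need not reflect the library left out. The count was 21 without TGF-β replicate 1, 29 without TGF-β replicate 2, 11 without TGF-β replicate 3, 22 without LIG replicate 1, 20 without LIG replicate 2 and 93 without LIG replicate 3. Of these genes, NQO1, LOC105374811, IL1B, TXNRD1, GCLM, IGFBP3, LOX, MEST and NPPB passed whichever library was left out. ANGPTL4, CXCL8, KRT17 and CPA4 missed the threshold without TGF-β replicate 3 (adjusted p from 0.0510 to 0.0531). LOC107986236, ESM1, COL3A1, TGFB2, MIR503HG and ACTC1 missed it in 3 to 5 of the 6 such fits, with adjusted p up to 0.208 for TGFB2 without TGF-β replicate 3. Without both libraries that stand apart, a comparison chosen after seeing the data, 497 genes changed, with 209 genes higher and 288 genes lower, and the 74 were among them in the same direction. The libraries left were the most alike of their groups (Pearson correlation 0.9977 and 0.998). Their spread was thus small by the choice itself, and calls from this comparison are no separate support.

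NRF2 target genes rose as a list by camera with its preset correlation (adjusted p = 5.58e-21), and missed the threshold at adjusted p = 0.078 with an estimated correlation. Fry called the list higher (fry adjusted p = 0.0184). Of 25 measured members, 6 rose over all genes tested, none fell and 19 did not pass; adjusted over the list alone, 18 rose. The median log2 change was 0.37, and 24 of 25 members had a change above 0. Among the 6 were NQO1, TXNRD1, GCLM, ME1 and HMOX1. TXNRD1, the cytosolic thioredoxin reductase, went from 42.0 ± 0.25 to 75.4 ± 2.21 FPKM (log2 change 0.83 ± 0.06, adjusted p = 0.00185). GCLM, a subunit of the enzyme that limits glutathione synthesis, went from 11.8 ± 0.69 to 19.7 ± 0.54 FPKM. HMOX1, the inducible haem oxygenase, went from 7.49 ± 0.77 to 11.4 ± 0.56 FPKM (adjusted p = 0.0290), a call lost without TGF-β replicate 1, TGF-β replicate 3, LIG replicate 1 or LIG replicate 2 (adjusted p up to 0.185). SLC7A11, the cystine transporter, was at 1.37 ± 0.13 and 3.33 ± 0.91 FPKM and did not pass (adjusted p = 0.0596), although it passed without LIG replicate 3 (adjusted p = 0.00326).

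**Figure D2:**
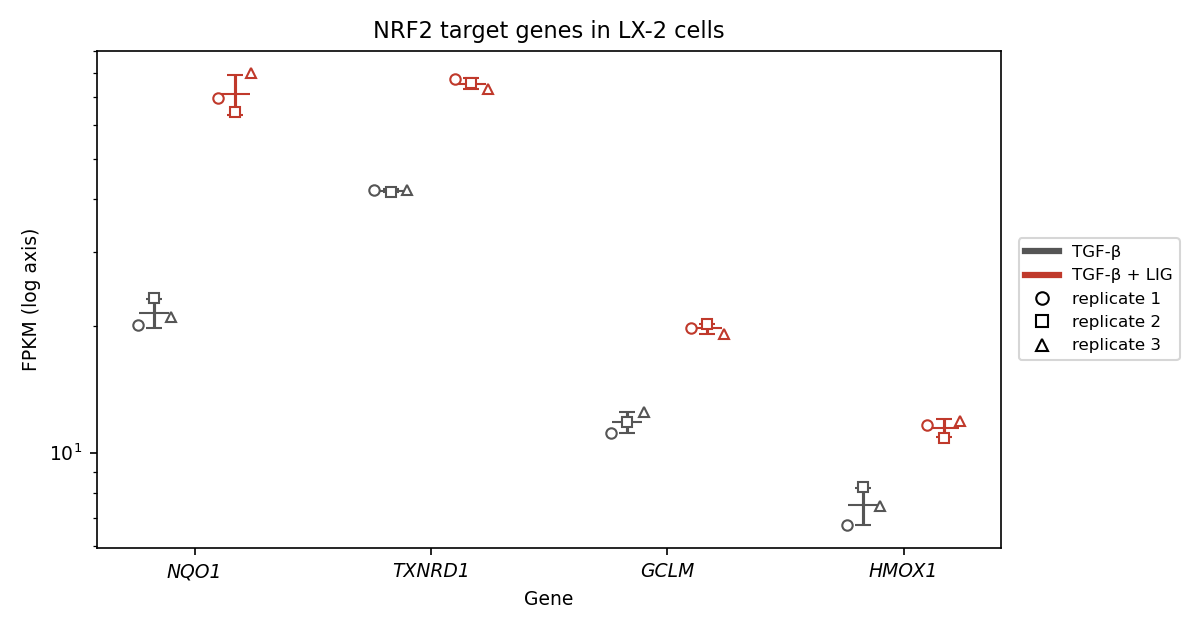
FPKM (log axis) of NQO1, TXNRD1, GCLM and HMOX1 in the 3 TGF-β libraries (grey) and the 3 TGF-β + LIG libraries (red). Symbols are libraries, long dashes are group means and error bars are SD (n = 3). NQO1 lies between 20.1 and 23.4 FPKM without LIG and between 64.7 and 79.8 FPKM with it.

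The ferroptosis-related list, which shares members with the NRF2 list, had a median log2 change of 0.13. HMOX1 rose and 24 of 25 members did not pass over all genes; adjusted over the list alone, 6 rose. The ferritin chains FTL and FTH1 were at 1068 ± 79.1 and 1091 ± 108 FPKM with TGF-β and at 1602 ± 201 and 1624 ± 264 FPKM with LIG, and neither passed over all genes (adjusted p = 0.118 and 0.213). Both have many processed pseudogenes, so their values carry the uncertainty of shared reads. The list passed camera (adjusted p = 7.64e-05), with adjusted p = 0.214 with an estimated correlation.

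Cytokine and inflammation genes under NF-kB control rose by camera (adjusted p = 8.35e-07; adjusted p = 0.098 with an estimated correlation), with a median log2 change of 0.13. Of 23 members, 2 rose and 21 did not pass; adjusted over the list alone, 8 rose. The 2 were IL1B, which encodes interleukin-1β and went from 32.6 ± 2.24 to 60.1 ± 4.03 FPKM (log2 change 0.86 ± 0.08, adjusted p = 0.00453), and CXCL8, which encodes the neutrophil attractant interleukin-8 and went from 10.3 ± 0.48 to 17.8 ± 1.39 FPKM. CXCL5 was at 1.6 ± 0.12 and 2.52 ± 0.20 FPKM (adjusted p = 0.0504). NFKB2 was at 17.2 ± 0.76 and 21.9 ± 1.73 FPKM (adjusted p = 0.151).

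Few single matrix genes passed over all genes. COL3A1, which encodes the α1 chain of type III collagen (chromosome 2, 188974320 to 189012746), went from 20.3 ± 2.41 to 9.96 ± 1.6 FPKM (log2 change -0.96 ± 0.12, adjusted p = 0.0144). This call was lost without TGF-β replicate 1 (adjusted p = 0.0667), TGF-β replicate 3 (0.0766) or LIG replicate 2 (0.0567). COL1A1, the most abundant collagen transcript here, was at 665 ± 41.0 FPKM with TGF-β and 503 ± 10.4 FPKM with LIG, a log2 change of -0.40 ± 0.08 that did not pass (adjusted p = 0.118). It passed without both libraries that stand apart (adjusted p = 0.000447; from 7.23e-05 to 0.662 over the alternative gene fits). COL5A2 was at 149.9 ± 6.66 and 114.8 ± 10.3 FPKM (adjusted p = 0.135), and COL5A1 at 128 ± 16.2 and 95.1 ± 9.88 FPKM (adjusted p = 0.264). Of 17 collagen genes, 1 fell and 16 did not pass over all genes; adjusted over the list alone, 8 fell. The median log2 change was -0.20 (camera adjusted p = 2.11e-08; adjusted p = 0.236 with an estimated correlation). COL1A2 was at 0.67, 0.71 and 6.73 FPKM in TGF-β replicates 1 to 3 and at 5.08, 3.28 and 3.24 FPKM in LIG replicates 1 to 3, and the difference did not pass (adjusted p = 0.802). Without TGF-β replicate 3 it was higher with LIG (adjusted p = 0.0451).

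Genes that process and crosslink collagen had a median log2 change of -0.17, and 19 of 21 members had a change below 0. LOX and P4HA1 fell and 19 did not pass; adjusted over the list alone, 9 fell. P4HA1, a catalytic subunit of collagen prolyl 4-hydroxylase, went from 34.3 ± 1.27 to 24.3 ± 0.68 FPKM (adjusted p = 0.0145). LOXL1 was at 15.1 ± 0.33 and 12.5 ± 0.52 FPKM (adjusted p = 0.200), and PLOD2, a lysyl hydroxylase, at 117 ± 0.64 and 99.7 ± 5.44 FPKM (adjusted p = 0.299). Among 23 matrix glycoproteins and proteoglycans, SPARC and THBS2 fell, 21 did not pass and, adjusted over the list alone, 6 fell; the median log2 change was -0.15. SPARC, a collagen-binding glycoprotein, went from 507 ± 2.89 to 368 ± 13.9 FPKM (adjusted p = 0.0435), and THBS2 from 37.0 ± 0.54 to 26.6 ± 2.37 FPKM (adjusted p = 0.0435). THBS1 was at 232 ± 12.1 and 150.7 ± 21.6 FPKM (adjusted p = 0.060; 0.0237 without LIG replicate 3) and FBLN2 at 13.99 ± 0.62 and 11.1 ± 0.31 FPKM (adjusted p = 0.0986). Both lists passed camera (adjusted p = 5.39e-11 and 3.15e-11), with adjusted p = 0.056 and 0.162 with an estimated correlation. The calls of P4HA1, SPARC and THBS2 were lost on leaving out any library but LIG replicate 3, with adjusted p up to 0.128, 0.324 and 0.262 without TGF-β replicate 3.

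Matrix proteases and their inhibitors did not pass camera as a list (median log2 change -0.05, adjusted p = 0.184), although fry found changes in either direction among them (adjusted p = 0.000146). TIMP3, a matrix-bound metalloproteinase inhibitor, went from 86.1 ± 0.79 to 56.6 ± 1.65 FPKM (log2 change -0.60 ± 0.06, adjusted p = 0.00552), a call lost without TGF-β replicate 3 (adjusted p = 0.0665). PLAT, tissue plasminogen activator, went from 48.7 ± 0.28 to 38.5 ± 0.50 FPKM (adjusted p = 0.0493), which passed in 1 of the 6 fits that leave out a library. The other 20 members did not pass, and adjusted over the list alone 2 fell. Among the 20 were MMP14 at 56.1 ± 2.56 and 65.1 ± 1.45 FPKM and PLAUR at 27.3 ± 1.83 and 33.3 ± 2.46 FPKM. Without both libraries that stand apart, 5 members rose, MMP14 and PLAUR among them (adjusted p = 0.0387 and 0.00667), and 2 fell.

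**Figure D3:**
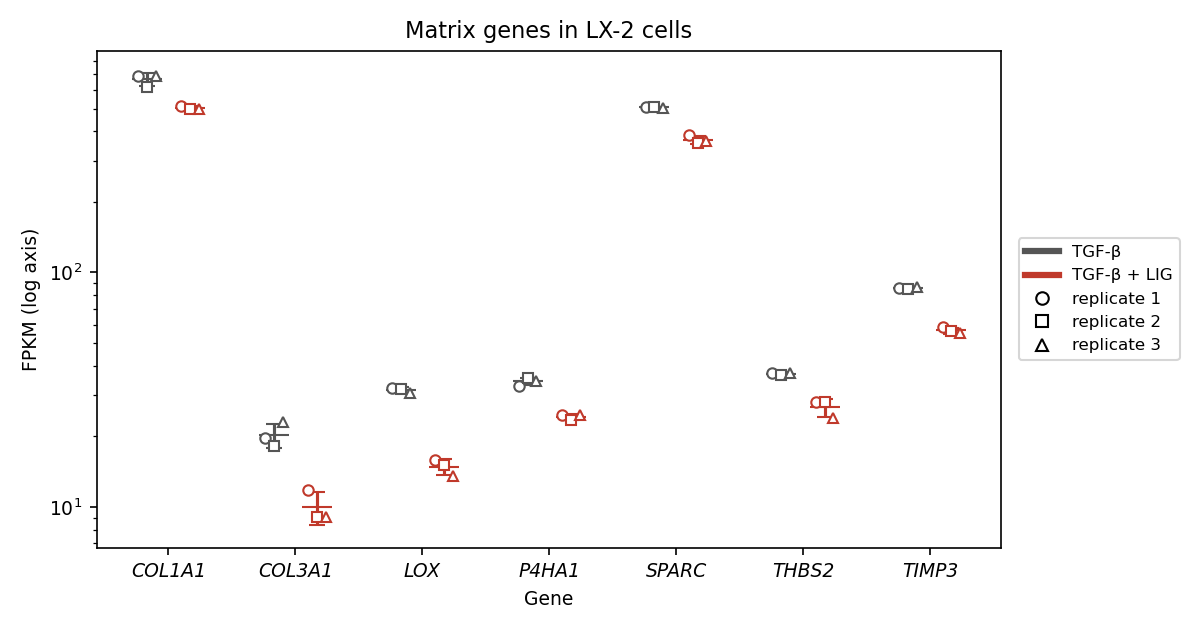
FPKM (log axis) of COL1A1, COL3A1, LOX, P4HA1, SPARC, THBS2 and TIMP3 in the 3 TGF-β libraries (grey) and the 3 TGF-β + LIG libraries (red). Symbols are libraries, long dashes are group means and error bars are SD (n = 3). The LIG libraries lie below the TGF-β libraries for each gene, and the change of COL1A1 did not pass over all genes (adjusted p = 0.118).

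Hypoxia response genes fell as a group by camera (adjusted p = 8.00e-12 with the preset correlation). This was the single list whose camera call held with an estimated correlation (adjusted p = 0.0419). Its estimate was -0.038, so correlation between members did not weigh against it. It was also among the 6 lists called by fry (fry adjusted p = 6.01e-05). Of 24 members, 5 fell, 1 rose and 18 did not pass; adjusted over the list alone, 11 fell and 2 rose. The median log2 change was -0.18. The 5 were LOX, AK4, P4HA1, BNIP3 and PDK1. LOX and P4HA1 are also the called members of the collagen processing list, and PDK1 that of the glycolysis list. Results of these lists are therefore not separate from each other. AK4, a mitochondrial adenylate kinase, went from 2.17 ± 0.07 to 1.05 ± 0.16 FPKM (adjusted p = 0.0127). BNIP3, a mitophagy receptor, went from 62.2 ± 3.57 to 41.3 ± 4.2 FPKM (adjusted p = 0.0290). ANGPTL4, which encodes an inhibitor of lipoprotein lipase and also responds to PPARs, went the other way, from 14.8 ± 0.73 to 27.2 ± 3.11 FPKM (adjusted p = 0.00632). Glycolysis genes had a median log2 change of -0.11 (camera adjusted p = 1.26e-07; adjusted p = 0.144 with an estimated correlation). Of 24, PDK1, which encodes a kinase that inhibits pyruvate dehydrogenase, fell from 1.51 ± 0.06 to 0.94 ± 0.06 FPKM (adjusted p = 0.0494). The other 23 did not pass, and adjusted over the list alone, 5 fell. LDHA was at 376 ± 17.8 and 286 ± 19.3 FPKM (adjusted p = 0.118). The PDK1 call was lost whichever library was left out (adjusted p up to 0.262 without TGF-β replicate 1), and those of AK4 and BNIP3 in 4 and 5 of the 6 such fits, with adjusted p up to 0.0766 and 0.182 without TGF-β replicate 3.

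Cholesterol biosynthesis genes and their regulators fell by camera (adjusted p = 6.45e-12; adjusted p = 0.056 with an estimated correlation), with a median log2 change of -0.15 and 23 of 26 members below 0. HMGCS1, the synthase at the entry of the mevalonate pathway, went from 90.8 ± 2.07 to 65.9 ± 2.31 FPKM (adjusted p = 0.0199). In all 2 of the 26 fell and 24 did not pass, SQLE among the 24 at 60.6 ± 2.45 and 48.5 ± 0.96 FPKM (adjusted p = 0.0928); adjusted over the list alone, 7 fell. The HMGCS1 call was lost on leaving out any library but LIG replicate 3, with adjusted p up to 0.178 without TGF-β replicate 3.

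YAP and TAZ target genes had a median log2 change of -0.17 (camera adjusted p = 5.31e-09, and 0.104 with an estimated correlation). Without both libraries that stand apart the median was nearer 0, at -0.10 (camera adjusted p = 4.27e-07). IGFBP3, F3 and TGFB2 fell and 24 of 27 did not pass; adjusted over the list alone, 7 fell. F3, the tissue factor that starts coagulation, went from 45.3 ± 0.95 to 28.96 ± 1.51 FPKM (adjusted p = 0.0058), and missed the threshold without TGF-β replicate 3 (adjusted p = 0.0607). TGFB2, which encodes the TGF-β2 ligand, went from 29.8 ± 1.46 to 15.7 ± 3.56 FPKM (adjusted p = 0.0435; up to 0.208, without TGF-β replicate 3). ANKRD1 was at 29.4 ± 1.49 and 22.9 ± 2.24 FPKM (adjusted p = 0.188).

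TGF-β SMAD target genes did not move as a list (median log2 change -0.01, camera adjusted p = 0.127), although fry found changes in either direction among them (adjusted p = 3.14e-05). CDKN2B, which encodes the cell cycle inhibitor p15, went from 6.47 ± 0.50 to 4.05 ± 0.26 FPKM (adjusted p = 0.0204), a call lost on leaving out any library but LIG replicate 3 (adjusted p up to 0.135 without TGF-β replicate 1). The other 27 did not pass over all genes; adjusted over the list alone, 5 fell and 3 rose. IL11 was at 246 ± 17.6 and 352 ± 38.9 FPKM (adjusted p = 0.0928) and PDGFB at 19.0 ± 0.69 and 15.3 ± 0.49 FPKM (adjusted p = 0.111). Of the pathway genes fixed for naming, SMAD7 was at 19.1 ± 0.46 and 20.1 ± 1.2 FPKM (adjusted p = 0.902) and TGFB1 at 129 ± 2.28 and 122 ± 7.40 FPKM (adjusted p = 0.871). CCN2, connective tissue growth factor, was at 443 ± 23.5 and 360 ± 23.2 FPKM (adjusted p = 0.288). The log2 changes of TGFBR1, TGFBR2, SMAD2 and SMAD3 were -0.03, 0.00, -0.01 and 0.01, and none passed (adjusted p from 0.973 to 0.998).

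Contractile genes fell by camera (adjusted p = 1.13e-06; adjusted p = 0.056 with an estimated correlation), with a median log2 change of -0.08 and 22 of 26 members below 0. None of the 26 passed by itself, over all genes or adjusted over the list alone. Over all genes, 11 fell without both libraries that stand apart and 13 fell with summed FPKM as a covariate, alternatives chosen after seeing the data. CALD1 was at 342 ± 4.4 and 274 ± 24.3 FPKM (adjusted p = 0.259), CNN1 at 11.1 ± 0.84 and 8.86 ± 0.72 FPKM (adjusted p = 0.264) and PALLD at 30.5 ± 0.08 and 26.1 ± 1.66 FPKM (adjusted p = 0.328). ACTA2, the α-smooth muscle actin used as a marker of activated stellate cells, was low, at 2.77 ± 0.66 and 2.97 ± 0.25 FPKM (adjusted p = 0.945). FN1 was at 1275 ± 238 and 960.5 ± 194.6 FPKM (adjusted p = 0.633) and TIMP1 at 126 ± 8.94 and 152 ± 22.6 FPKM (adjusted p = 0.563). PDGFRB was at 4.99 ± 0.72 and 3.32 ± 0.59 FPKM (adjusted p = 0.257). Without both libraries that stand apart, FN1, CCN2 and PDGFRB were lower and TIMP1 higher with LIG (adjusted p = 0.000893, 0.00496, 0.00992 and 0.00886). Over the alternative gene fits their adjusted p ranged from 0.000486 to 0.9995, from 0.000269 to 0.830, from 0.000692 to 0.764 and from 0.0023 to 0.999.

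Interferon response genes had a median log2 change of -0.10 (camera adjusted p = 1.39e-08; adjusted p = 0.144 with an estimated correlation). GBP1, an interferon-induced GTPase, went from 65.6 ± 1.89 to 50.9 ± 0.38 FPKM (adjusted p = 0.0435; up to 0.253, without TGF-β replicate 1) and 33 of 34 did not pass; adjusted over the list alone, 2 fell. S phase genes had a median log2 change of -0.04 (camera adjusted p = 0.00204; adjusted p = 0.254 with an estimated correlation), and none of 41 passed. Lysosome and autophagy genes had a median of 0.07 (camera adjusted p = 0.0333; adjusted p = 0.647 with an estimated correlation). There BNIP3 fell and 42 of 43 did not pass; adjusted over the list alone, 1 rose and 2 fell. That list's call ended without TGF-β replicate 1 (adjusted p = 0.109) and without LIG replicate 3 (adjusted p = 0.472). It also ended without both libraries that stand apart (adjusted p = 0.178) and with summed FPKM as a covariate (adjusted p = 0.0775). By camera with its preset correlation, leaving out 1 library ended none of the other 14 list calls. The list calls by fry and by camera with an estimated correlation were not repeated without a library.

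The other 14 lists with at least 5 measured members, besides TGF-β SMAD targets and matrix proteases, did not pass camera. Of them, cytosolic ribosomal protein genes had a median log2 change of 0.05 (adjusted p = 0.426) and nuclear oxidative phosphorylation genes 0.06 (adjusted p = 0.325). The estimated correlation between members was 0.977 and 0.882, and with it the adjusted p was 0.963 for both, so the following calls rest on the preset correlation. Both passed in the other direction without LIG replicate 3, with medians of -0.085 and -0.054 (adjusted p = 2.49e-06 and 0.00115). Both also passed in the upward direction without TGF-β replicate 2 (adjusted p = 0.000624 and 0.00104), LIG replicate 1 (0.00392 and 0.00637) or LIG replicate 2 (0.000372 and 0.00193). Replication-dependent histone genes had a median of 0.12 (adjusted p = 0.0816), and passed without TGF-β replicate 2 (0.0438), TGF-β replicate 3 (0.0327) or LIG replicate 2 (0.0203). Medians were 0.06 for heat shock genes (adjusted p = 0.531), 0.03 for ATF4 integrated stress response genes (0.164) and 0.03 for p53 target genes (0.934). They were 0.03 for G2 and mitosis genes (adjusted p = 0.934), 0.02 for apoptosis regulators (0.594) and 0.01 for immediate early genes (0.571). The median was -0.02 for ER chaperone genes (camera adjusted p = 0.124). That list passed without LIG replicate 3 (0.0309) and with summed FPKM as a covariate (0.0168). Fatty acid and lipid droplet genes (median 0.01, adjusted p = 0.626), metallothionein genes (0.06, 0.934), mitochondrially encoded genes (0.00, 0.934) and stellate cell quiescence genes (0.02, 0.934) had a median and mean above 0 while camera set them below the other genes. Adjusted over the list alone, 4 ATF4 genes and 1 quiescence gene rose, 1 heat shock gene fell, 1 gene rose and 1 fell in each of the immediate early, p53 and fatty acid lists, and no member passed in the other 8. Over all genes, single members passed in some of these lists, ANGPTL4 among fatty acid genes. FOSL1, an AP-1 subunit, rose from 51.9 ± 3.49 to 80.8 ± 4.25 FPKM and EGR2 fell from 6.87 ± 0.20 to 4.67 ± 0.45 FPKM among immediate early genes. The co-chaperone DNAJB4 fell from 24.5 ± 0.92 to 17.9 ± 1.08 FPKM and the p53 target PLK2 from 76.7 ± 3.35 to 58.4 ± 1.65 FPKM. The calls of these 4 genes were lost in 3 to 5 of the 6 fits that leave out a library.

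Markers of hepatocytes, endothelial cells, macrophages and leukocytes were mostly near 0. Of the hepatocyte markers in the table, 2 of 14 reached a mean of 1 FPKM, SERPINA1 at 3.83 ± 0.28 and 3.93 ± 0.84 FPKM and ASGR1 at 2.85 ± 0.33 and 3.80 ± 0.72 FPKM. Of the endothelial markers 2 of 11 did, TIE1 at 13.8 ± 0.54 and 14.9 ± 0.45 FPKM and EGFL7 at 3.48 ± 0.40 and 3.26 ± 0.46 FPKM. Of the macrophage and leukocyte markers 1 of 13 did, CD68 at 13.1 ± 1.1 and 14.3 ± 0.81 FPKM. These lists, and that of aryl hydrocarbon receptor targets, had too few members for the list test. Among the receptor's targets, CYP1A1 was at 0.26 ± 0.04 and 0.22 ± 0.01 FPKM and TIPARP at 11.3 ± 0.25 and 13.2 ± 0.99 FPKM, while NQO1 rose. Cholangiocyte and epithelial markers were less uniformly low, as 5 of 10 with values reached a mean of 1 FPKM. These 5 were tested and had a median log2 change of -0.26 (camera adjusted p = 0.000112, and 0.132 with an estimated correlation). None of them passed over all genes; adjusted over the list alone, KRT8, KRT18 and SOX9 fell. KRT8 was at 174 ± 7.29 and 134 ± 15.3 FPKM and KRT18 at 207 ± 12.1 and 164 ± 20.6 FPKM.

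**Figure D4:**
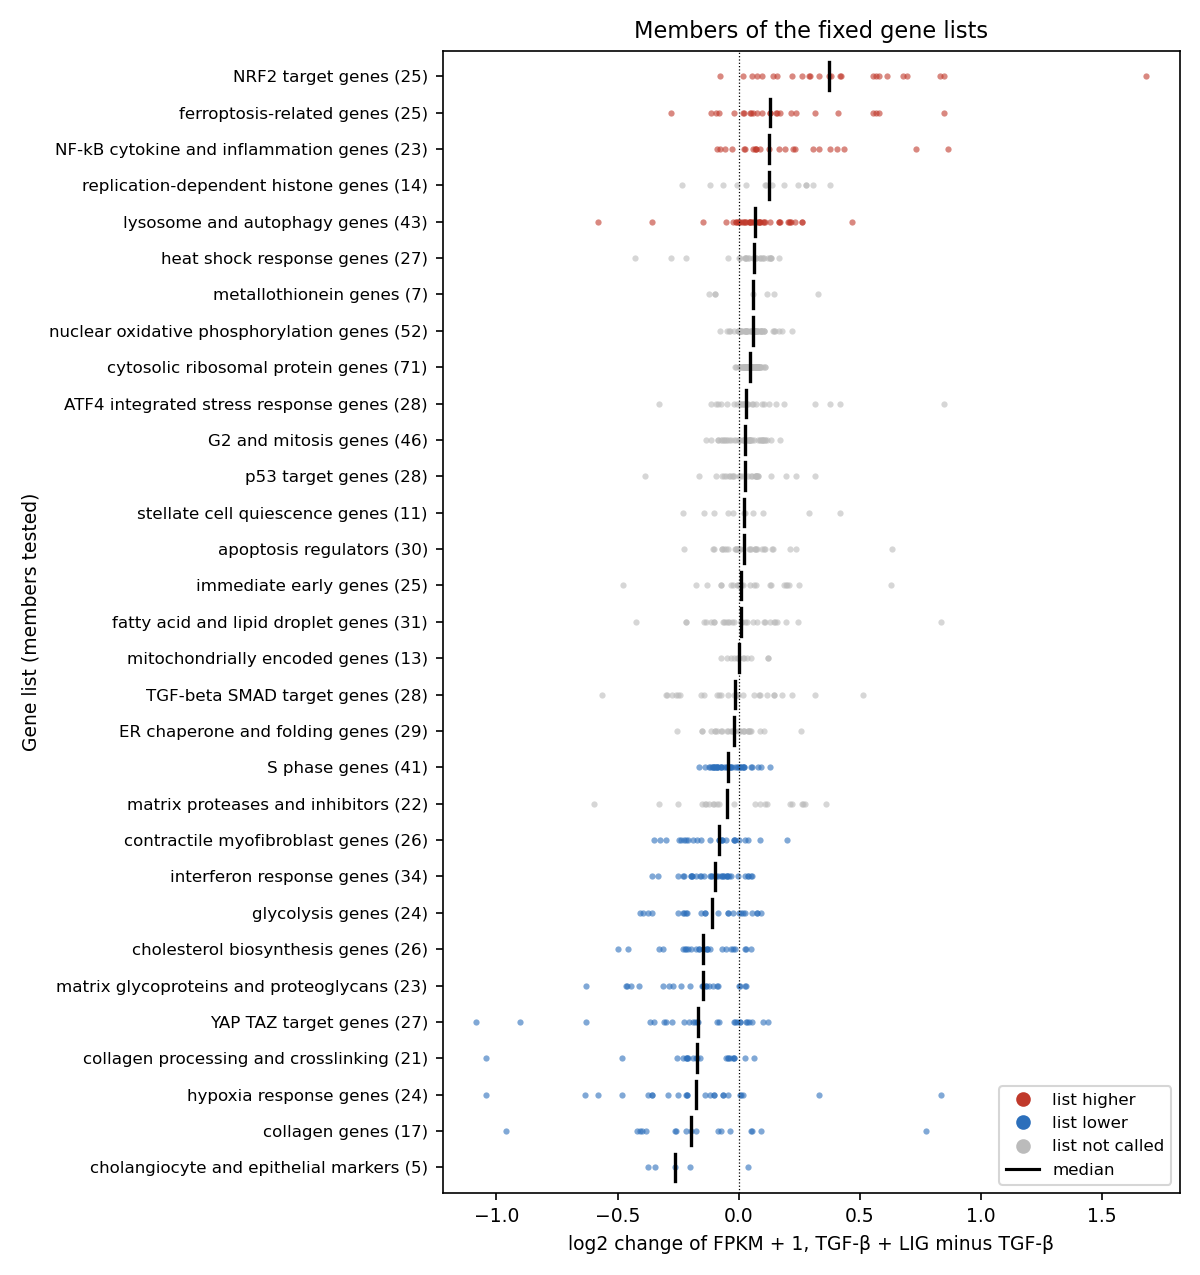
Log2 change of FPKM + 1 (horizontal, TGF-β + LIG minus TGF-β) of each member of the 31 gene lists tested, with the number of members in parentheses. Points are genes, black marks are list medians, and colour shows whether camera with its preset correlation called the list higher (4 lists, red), lower (11 lists, blue) or neither (grey); with an estimated correlation the hypoxia list alone was called.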

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

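Leaving out both libraries that stand apart, the summed FPKM covariate and voom on recovered fragments were chosen after seeing the data. The 74 genes kept their direction under each alternative fit in which they were tested, library quality weights included. Pseudocounts, a mean FPKM of at least 5, TPM, median centring, no trend, robust estimation and voom gave between 63 and 86 genes changed. Of the 74 genes, 59 were among those called with TPM, and between 62 and 74 were called in the others of these fits. TGFB2, THBS2, EGR2, DNAJB4, PDK1 and PLAT did not pass with TPM (limma adjusted p from 0.0542 to 0.144). TPM raised the share of higher calls from 27.0% to 34.9%.

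Of the 74 genes (20 higher, 54 lower), 5 (2 higher, 3 lower) also had a log2 change of at least 1, a stricter rule by construction. Without a filter 14 genes changed (5 higher, 9 lower), with more genes tested. Quantile normalization gave 107 genes, 32 of them higher. Library quality weights gave 1891 (1117 higher, 774 lower), leaving out both libraries that stand apart 497 (209 higher, 288 lower), and summed FPKM as a covariate 762 (340 higher, 422 lower); the cause was not tested. Leaving out 1 library gave 11 (without TGF-β replicate 3) to 93 genes (without LIG replicate 3), 6 to 24 higher and 5 to 69 lower, and 10 genes were called in all 6 such fits.

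Of the 15 lists, camera with an estimated correlation called 1 (0 higher, 1 lower) and fry 6 (2 higher, 4 lower). Fry called the NRF2 and NF-kB lists higher and the hypoxia, cholesterol, collagen processing and contractile lists lower (fry adjusted p from 6.01e-05 to 0.0306). Both allow for correlation between genes in these libraries. For the contractile list the estimate, 0.0097, lay close to the preset 0.01, yet the camera adjusted p went from 1.13e-06 to 0.056. There the size of the correlation does not account for the lost call. A call lost with an estimated correlation thus does not by itself show that the members of a list are correlated. Leaving out 1 library gave 3 to 7 lists higher. Without LIG replicate 3 the ribosomal protein and oxidative phosphorylation lists were lower with LIG, with medians of -0.085 and -0.054. Their highest medians, without TGF-β replicate 2, were 0.13 and 0.13. Without both of these libraries, the 2 that stand apart, the medians were -0.0006 and 0.014. Neither list then passed camera with its preset correlation (adjusted p = 0.210 and 0.937). The cause of the opposite calls was not tested.

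The replicate numbers are not said to pair the libraries. Deviations of same-numbered libraries correlated at 0.47, -0.57 and -0.34 for numbers 1 to 3, and TGF-β replicate 2 correlated best with LIG replicate 3 (0.68). With the replicate block 22 genes changed (9 higher, 13 lower) and 15 lists.

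Named genes were compared under each alternative gene fit and lists under the same fits except library quality weights, besides the other list tests. Of the gene results 2356 stayed on their side of the threshold, 229 passed newly, 170 no longer passed and 0 reversed. Of the list results these were 603, 18, 27 and 2. Depth limits mainly the 0.51% of genes with fewer than 30 fragments in a library, LOC107986236 among them.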

Other observations

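The tests of the 2 libraries that stand apart as a cause of the list changes, of GC content and of sequencing depth, and the comparison of COL1A2 with LIG treatment, were chosen after the results were seen.

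The following 6 called genes lie outside the naming rule and were picked by hand after their values were seen, so they stand for no class of genes. EDN1 (endothelin-1) fell from 20.2 ± 1.19 to 12.9 ± 1.09 FPKM, FGF1 from 19.8 ± 0.78 to 14.7 ± 0.42 FPKM, CCBE1 from 19.2 ± 0.44 to 14.4 ± 0.50 FPKM and TNFRSF11B (osteoprotegerin) from 7.81 ± 0.70 to 4.78 ± 0.40 FPKM (SD, n = 3 each; limma adjusted p = 0.0175, 0.0313, 0.0313 and 0.0233). ALAS1, which limits haem synthesis, rose from 25.8 ± 0.66 to 38.3 ± 2.67 FPKM and CASP4, an inflammatory caspase, from 20.3 ± 0.61 to 28.1 ± 1.73 FPKM (adjusted p = 0.0145 and 0.0290). Each of these 6 calls was lost on leaving out any library but LIG replicate 3, with adjusted p up to 0.217 for FGF1 without LIG replicate 2.

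The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 74 genes, a number reached by 1 of the 10 splits, and the highest of the others was 0. It gave 15 lists, also reached by 1 of the 10, and the highest of the others was 11. The lowest of the others was 5, so every split that mixed the groups also gave list calls. Each mixed split still held more libraries of one group on one side, so part of the group difference remained in it. Its list calls therefore cannot show how often camera with its preset correlation calls lists without a LIG effect. Such a list call was not taken as evidence of a LIG effect by itself.

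Camera with an estimated correlation called the hypoxia list alone. Fry called the NRF2, hypoxia and collagen processing lists, but not the collagen or matrix glycoprotein lists (fry adjusted p = 0.190 and 0.184). By camera with its preset correlation, NRF2 targets were higher and matrix and hypoxia genes lower with LIG. Were this due to the 2 libraries that stand apart, the list medians would shrink without them, but the NRF2 median went from 0.37 to 0.31 (a ratio of 0.845, the smallest of 5 lists) and the hypoxia median from -0.18 to -0.16. A bias of the changes with gene length and GC content would shrink the list medians once that trend is removed, but the NRF2 median kept a ratio of 0.957 to its value and the hypoxia median 0.993. The design names LIG as the difference between the groups, so an effect of LIG is a candidate explanation, untested beyond these libraries. A difference in culture or handling between the groups stays open.

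TGF-β replicate 2 and LIG replicate 3 deviated together from their groups. Total fragments differed by at most 1.022 times, which argues against depth. The mean deviation had a Spearman rho of 0.166 with GC content across genes, but of -0.092 in TGF-β replicate 2 and 0.327 in LIG replicate 3, opposite signs that argue against GC content as the shared cause. With gene length the rho was -0.714 across genes, which are not independent replicates: of 4 classes of length, the shortest genes (median 1637 bp) lay at 0.13 and the longest (median 8679 bp) at -0.09 on the log2 scale. Recovery of fragments that depends on gene length, as from RNA of another integrity, is therefore a candidate explanation, and no biological explanation was tested.

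COL1A2 and DCN differed about 10 times between TGF-β replicates, DCN at 0.12, 0.13 and 1.43 FPKM in replicates 1 to 3. TGF-β replicate 3 had no LIG and held 9.5 times the COL1A2 fragments of the higher of the other TGF-β replicates, so LIG cannot account for that difference; this follows from the pattern itself and is no separate test. In 13 fibroblast markers not used to notice the pattern (of 22 listed, 8 were left out as expressed in these cells and 1 was not in the table), TGF-β replicate 3 had 2.43 times the fragments of TGF-β replicates 1 and 2 (95% exact interval 2.00 to 2.96), and at least 1.80 times with any 1 marker left out. This ratio did not cover the LIG libraries. The 13 markers summed to 108, 84 and 233 fragments in TGF-β replicates 1 to 3. In LIG replicates 1 to 3 they summed to 207, 134 and 138, the last 2 little above TGF-β replicate 1. Of the 233 fragments, 111 were of MXRA5 and 89 of ABCA8, although 11 of the 13 markers were highest there among TGF-β replicates. RNA of a fibroblast-like source in TGF-β replicate 3 may explain the difference between TGF-β replicates. For the LIG libraries such a source was not tested. A minority of LX-2 cells with such expression and RNA from another sample stay open.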
